A study of Homo sapiens with 10 samples.

How the data were processed

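Tumour biopsies of 5 patients with melanoma, each sampled at baseline and during treatment with an antibody against PD-1, were analysed as 10 samples. Per the labels' protocols, RNA was extracted with the mirVana kit, enriched for polyadenylated transcripts, made into libraries with a TruSeq RNA kit and sequenced from both ends. The authors deposited one table of FPKM values per gene and sample, that is fragments per kilobase of transcript and per 1000000 mapped fragments. The submitters' processing notes name the build hg19 and the tools TopHat2, TopHat and Cuffnorm, without saying what each did. Their versions, the annotation and whether values were rescaled between samples are not given in the sources used here.

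The table listed 25268 entries. In 28 of them a calendar date stood in place of a gene symbol, and these were left out, leaving 25240 genes. No 2 samples had identical columns. Of the symbols, 95.5% were found in current or older gene name tables, and these tables (assembly GRCh38.p14) were used only for names and neighbouring genes, with no coordinates printed because the build differs. FPKM values hold no whole counts, so depth per sample is unknown and no counting interval or detection floor is given. Among 93781 values with 7 significant digits, 97.3% ended in 5, as the mean of 2 values with fewer digits would. The table was used as deposited, with no further scaling, for the main results. In it the upper quartiles of the tested genes lay between 19.1 and 21.3 FPKM, while the totals were set by genes for small RNAs.

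Samples were grouped by their titles, and the patient number in the title paired them. The pairing was checked: deviations from the group means correlated at 0.605 to 0.824 within pairs and at -0.427 to 0.291 between samples of different patients, across genes, and each sample matched its own partner best. Because the labels name the patient, the model held patient as a block, and the fit without it was an alternative.

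Genes with at least 0.5 FPKM in at least 3 of the 10 samples were transformed to log2(FPKM + 1) and tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes on this scale understate the change of low genes. Intervals are 95% confidence intervals of the moderated fit. Differences of paired values were tested with the exact two-sided sign-flip permutation test over all 32 sign patterns, whose smallest p is 2 of 32. The patients are separate donors, and each biopsy was sequenced as 1 sample. The titles do not say whether both biopsies of a patient came from the same tumour. The tumour sampled, sampling within a tumour, the time point and library preparation therefore cannot be separated within a pair.

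Before the data were examined, the design, the alternatives, the rule for named genes and 31 gene lists were fixed, 381 genes in all, of which 380 were in the table. The lists cover PD-1 ligands, interferon receptors and signalling, interferon gamma response, type I interferon response, interferon feedback regulators, MHC class I and class II presentation, T cells, cytotoxic lymphocytes, checkpoint and exhaustion genes, regulatory T cells, other inhibitory ligands, B and plasma cells, NK cells, macrophages and monocytes, dendritic cells, neutrophils, the melanocytic lineage, dedifferentiated melanoma, proliferation, fibroblasts, endothelial cells, keratinocytes, adipocytes, skeletal muscle, hepatocytes, red blood cells, immediate early and stress genes, hypoxia and glycolysis, histone genes without a poly(A) tail and housekeeping genes. The 30 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 between genes. Camera compares a list with the other genes. Beside it stood camera with the correlation estimated from the data and fry, whose directional p asks whether a list's genes move one way on balance. With 5 pairs the estimated correlation also holds changes that a list's genes share within a patient.

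Named genes were chosen by rule: CD274, PDCD1LG2 and the measured interferon receptor and signalling genes; genes past the threshold and changed alike in all 5 pairs, of which there were 0; in their place up to 10 genes higher and 10 lower with the smallest unadjusted p; and in each list described in detail the 3 members with the smallest p and the most abundant one. Uncharacterised loci, microRNA and snoRNA genes and unnamed reading frames were left out of the third part. 1 gene that the rule selects is not reported here singly, but it entered the tests and counts of its lists. Genes whose values could bear on a donor's identity, such as those on the Y chromosome, XIST, variable segments of immune receptors and genes with common germline deletions, were left out throughout.

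Alternatives were a pseudocount of 0.1, no filter, a stricter filter of 1 FPKM in 5 samples, no patient block, patient as a random effect, scaling each sample to a total of 1000000, to equal upper quartiles or by quantiles, sample weights, eBayes without trend and robust options, the 2 other list tests and leaving out each pair. For the random effect, lists were tested with camera's pre-ranked form, since camera takes no correlation between samples. Leaving out small RNA genes, and scaling to a total of 1000000 without them, were added after seeing the data.

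The fit was tested on simulated data first. Samples were drawn with the means and spread of the real genes, and 200 of 15184 genes were changed by 1, 2 or 3 on the log2 scale. It recovered 55.2% of 67, 80.6% of 67 and 74.2% of 66 such genes, called 8 unchanged genes, and gave an unadjusted p under 0.05 to 5.04% of unchanged genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Correlations across patients were left out, as the study holds fewer patients than the minimum set for them.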

Results

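Melanoma biopsies taken before and during treatment with an antibody against PD-1, the inhibitory receptor of T cells, were profiled by paired-end sequencing of polyadenylated RNA. Each of 5 patients gave a baseline and an on-treatment biopsy, so that 10 samples formed 5 pairs. The series asks how interferon receptor signalling relates to the expression of the PD-1 ligands PD-L1, encoded by CD274, and PD-L2, encoded by PDCD1LG2. Expression was given as FPKM for 25240 usable genes, of which 15184 reached at least 0.5 FPKM in at least 3 samples and were tested. Between 12536 and 14444 genes reached 0.5 FPKM in a sample. Read depth was not recoverable from these values and is unknown. The summed FPKM ranged from 607546 to 12177900, and genes for small RNAs held between 10.3% and 95.6% of it. Without them the sums lay between 454668 and 690522. Both samples of replicate 1 stood apart, with 12536 and 13021 genes at 0.5 FPKM and small RNA shares of 10.3% and 64.0%. Changes below are on-treatment minus baseline within a pair, on the log2(FPKM + 1) scale, which understates the change of genes with low values.

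CD274 and PDCD1LG2, neighbouring genes with 0 protein-coding genes between them, were both weakly expressed, and neither differed between the time points by more than the spread between patients. CD274 had a mean of 0.785 ± 0.690 FPKM at baseline and 0.911 ± 0.706 on treatment (SD, n = 5). PDCD1LG2 had 1.53 ± 1.21 FPKM at baseline and 1.55 ± 1.68 on treatment (SD, n = 5). The 5 patients moved in different directions. CD274 differed by 0.76, 0.64, 0.02, -0.17 and -0.79 in replicates 1 to 5, and PDCD1LG2 by 0.46, 0.85, -0.31, -0.38 and -0.87. The paired limma estimate was 0.09 for CD274 (SE 0.24, 95% CI -0.46 to 0.64, adjusted p = 1.00) and -0.05 for PDCD1LG2 (SE 0.26, 95% CI -0.65 to 0.55, adjusted p = 1.00). Adjusted over the list alone, 0 of these 2 ligands passed, with an adjusted p of 0.852 for each, and 0 of 2 had an unadjusted p under 0.05. Their mean as a list was 0.02, with positive values in 2 of 5 pairs, and 2 genes were too few for camera. The intervals do not exclude a difference of 0.64 in CD274 or of -0.65 in PDCD1LG2. Leaving out replicate 1 turned the CD274 estimate to -0.07, and leaving out replicate 5 turned that of PDCD1LG2 to 0.15.

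The change of CD274 exceeded that of PDCD1LG2 in 4 of 5 pairs. The mean difference was 0.14 ± 0.22 (SD, n = 5 pairs), with a range from -0.22 to 0.33. The exact two-sided sign-flip permutation test gave p = 0.25. With 5 pairs the smallest p possible is 2 of 32 sign patterns, so no single comparison of this kind could reach 0.05.

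Among the receptors and signal transducers of the interferon pathways, the smallest unadjusted p belonged to a higher IRF9 and a lower IFNGR1, and neither passed the test. IRF9, the DNA-binding subunit of the type I interferon complex ISGF3, had 28.2 ± 9.77 FPKM at baseline and 39.2 ± 15.3 on treatment (SD, n = 5), with a log2 difference of 0.43 (SE 0.21) and higher values in 4 of 5 pairs. IFNGR1, the ligand-binding chain of the interferon gamma receptor, had 30.9 ± 5.81 FPKM at baseline and 24.3 ± 1.77 on treatment (SD, n = 5), a log2 difference of -0.31 (SE 0.16), with a higher value in only 1 of 5 pairs. STAT3 differed by 0.38 (SE 0.23), IRF1 by 0.36 (SE 0.39), JAK1 by 0.21 (SE 0.18), STAT2 by 0.15 (SE 0.19) and TYK2 by 0.12 (SE 0.15). The receptor chains IFNGR2, IFNAR1 and IFNAR2 differed by -0.07 (SE 0.20), 0.04 (SE 0.20) and -0.01 (SE 0.20), and the kinase JAK2 by -0.02 (SE 0.24). IRF1, a transcription factor induced by interferon gamma, spread widely between patients, with pair differences of 1.80, 1.23, 0.02, -0.34 and -0.88.

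Of these 12 genes, 0 passed an adjusted p of 0.05 in limma over all genes, and 0 passed when adjusted over the list alone, with 0 at an unadjusted p under 0.05, where the smallest adjusted p was 0.507 for IRF9 and IFNGR1. As a group they did not stand apart from other genes (camera adjusted p = 0.333, mean log2 difference 0.12), but without replicate 5 the list passed (adjusted p = 0.0152, mean 0.22). By the exact sign-flip permutation test over n = 5 pairs, IFNGR1 gave p = 0.125 and IRF9 p = 0.188.

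**Figure D1:**
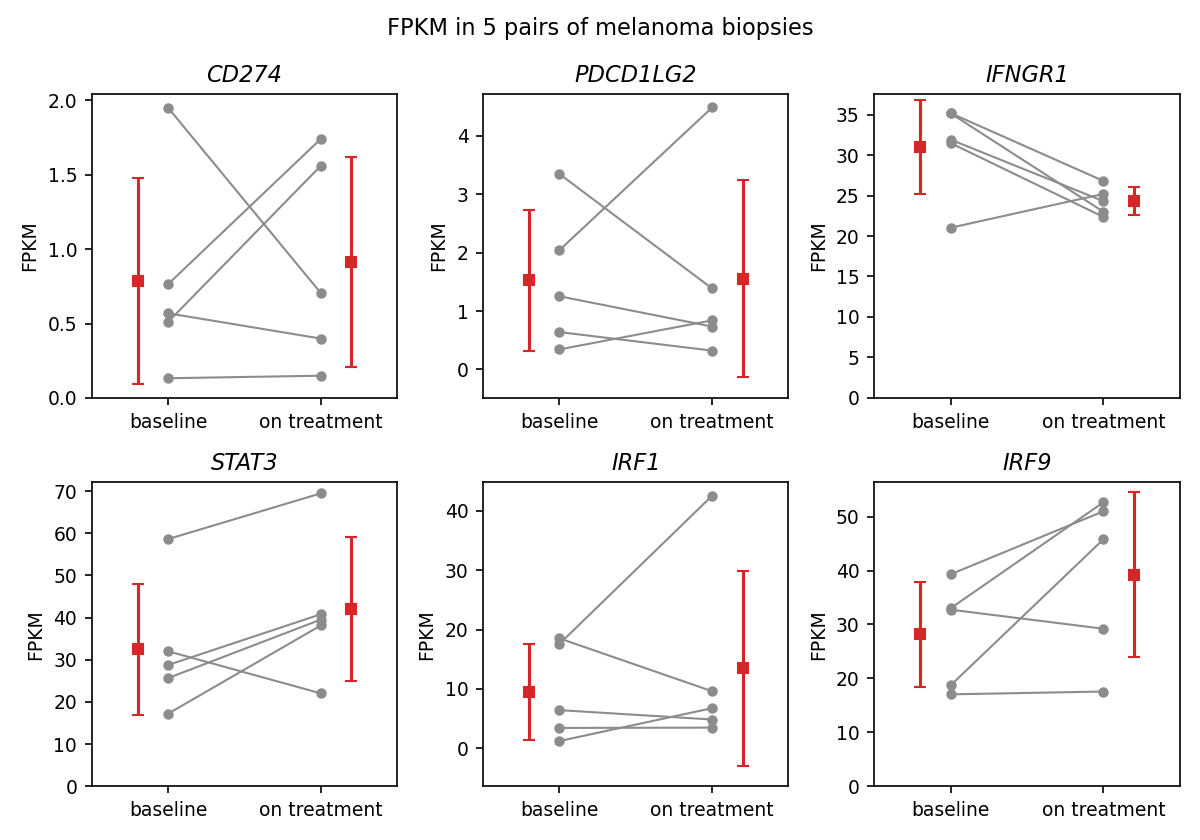
FPKM (vertical axes, linear) of 6 genes at baseline and on treatment; each grey line joins the 2 biopsies of 1 patient, and red squares with bars give the mean and SD of 5 samples. CD274, PDCD1LG2 and IRF1 moved in different directions between patients, while IFNGR1 was lower on treatment in 4 of 5 pairs and IRF9 and STAT3 higher in 4 of 5, none past an adjusted p of 0.05.

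Over the whole transcriptome, 0 of 15184 genes passed an adjusted p of 0.05 in limma with patient as a block. The smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 347 genes, 230 higher and 117 lower on treatment, against 759 that chance alone would give on average. Of 14 drawn splits of the samples that part all 5 pairs, 11 gave at least 347, the real one among them. The others ran from 254 to 1528 genes, so 347 is no clear shortfall. Without the patient block 0 genes passed and 10 lay under an unadjusted 0.05. All 5 pairs moved in the same direction for 695 genes, or 4.58%, against 6.25% by chance. The patient term accounted for a median of 85.0% of a gene's sum of squares, treatment for 1.18% and the residual for 12.3%. These shares are not corrected for the number of coefficients in each term, which was larger for patient than for treatment. Noise would therefore also give patient the larger share of these 2. The patient term also holds whatever else the samples of a pair share. On samples simulated with the means and spread of these genes, the same fit recovered 55.2%, 80.6% and 74.2% of genes differed by 1, 2 and 3 on the log2 scale. That simulation changed 200 genes at once, each by the same amount in every pair. Its recovery therefore does not carry over to fewer or less uniform changes. In the real data FXYD3, at 2.28, and RNU4ATAC, at -3.12, did not pass.

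None of the genes with the smallest unadjusted p passed. Higher on treatment in all 5 pairs were BAALC (15.5 ± 14.7 to 43.1 ± 44.6 FPKM, SD, n = 5), with a log2 difference of 1.15 (SE 0.19), RAB27A, a small GTPase of melanosome transport, with 0.69 (SE 0.15), and CSPG4, a melanoma-associated proteoglycan, with 0.88 (SE 0.20). FXYD3, a regulator of the sodium pump, differed by 2.28 (SE 0.52). GPR153, SH2B3, ITM2A, TAF15, LIMK2 and SIAE differed by between 0.54 and 0.65, also higher in all 5 pairs. Lower in all 5 pairs were the proton pump subunit ATP6V0D2, by -0.99 (SE 0.21), the RAB27A effector SYTL2, by -0.82 (SE 0.19), and the lysosomal protease CTSK, by -1.18 (SE 0.29), from 326 ± 199 to 171 ± 131 FPKM (SD, n = 5). MTURN, ECT2, FCGR2B and ELL2 differed by between -0.58 and -0.52, and BNIP3 by -0.96 (SE 0.28), all lower in 5 of 5 pairs. BEX5 differed by -0.78 (SE 0.24). The small nuclear RNA gene RNU4ATAC had the largest difference of these, -3.12 (SE 0.75), and was 0 in most on-treatment samples.

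Targets of interferon gamma differed strongly between time points, but in opposite directions between patients. The list's 19 measured members, among them the chemokines CXCL9, CXCL10 and CXCL11, differed on average by 1.70, 0.98, 0.18, -0.39 and -1.15 in replicates 1 to 5. The mean over pairs was 0.26, with an SD of 1.12, and 16 of the 19 members had a positive estimate. WARS, an interferon-induced tRNA synthetase, had 143 ± 46.6 FPKM at baseline and 304 ± 232 on treatment (SD, n = 5), a log2 difference of 0.72 (SE 0.35), PSME2 differed by 0.33 (SE 0.19) and ICAM1 by 0.32 (SE 0.23). The list did not pass camera (adjusted p = 0.130), and 0 members passed over all genes or adjusted over the list alone. It passed with each sample scaled to a total of 1000000 (mean 0.47, adjusted p = 3.34e-10) and with sample weights (mean 0.40, adjusted p = 0.0145). Small RNAs set that total, and with a total of 1000000 without them the list did not pass (mean 0.34, camera adjusted p = 0.220). Without replicate 5 its adjusted p was 2.74e-08 with a mean of 0.62, without replicate 4 it was 0.0222 with 0.43, and without replicate 1 the mean turned to -0.10.

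The 22 genes of the type I interferon response showed no common direction, with 10 higher and 12 lower estimates and pair changes of 0.96, 0.04, 0.16, 0.18 and -1.50 (camera adjusted p = 0.668). With 1 pair left out the list passed in opposite directions, at -0.28 without replicate 1 and at 0.34 without replicate 5. IFI6 was the most abundant at 791 ± 588 FPKM at baseline and 1246 ± 1357 on treatment (SD, n = 5), a log2 difference of 0.45 (SE 0.41), while IFIT1 differed by -0.52 (SE 0.42) and OAS2 by 0.27 (SE 0.28). The interferon gamma list exceeded the type I list in 4 of 5 pairs, by 0.30 ± 0.60 (SD, n = 5 pairs), with p = 0.312 in the exact sign-flip permutation test. The 12 feedback regulators, including the SOCS and PTPN genes, differed by a mean of 0.04 (camera adjusted p = 0.734).

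Antigen presentation genes likewise diverged by patient. The 14 genes of the MHC class I list had pair changes of 0.55, 0.20, 0.20, -0.27 and -0.59 (camera adjusted p = 0.998), with B2M at 0.40 (SE 0.31), HLA-B at -0.36 (SE 0.23) and NLRC5 at 0.23 (SE 0.24). The mean and median of that list were positive, 0.02 and 0.07, where camera's direction was down. Without replicate 5 the MHC class I list passed (mean 0.17, camera adjusted p = 0.0246). The 8 MHC class II genes differed by 1.18, 0.79, 0.69, -1.73 and -0.98 (camera adjusted p = 0.734), with CD74 at 0.41 (SE 0.62), HLA-DMB at -0.42 (SE 0.31) and HLA-DMA at -0.22 (SE 0.39). HLA, IFIT, GBP, globin and histone genes have near-identical relatives that may share reads, so their single values are uncertain.

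T-cell and cytotoxic genes were higher on treatment in some patients and lower in others, and of the lymphocyte lists only that of regulatory T cells passed. Without replicate 5 the T-cell and cytotoxic lists passed too, with means of 0.35 and 0.45. The 15 T-cell genes differed by 0.83, 0.65, 0.05, -0.34 and -0.61 in replicates 1 to 5 (camera adjusted p = 0.333), with CD3E at 0.35 (SE 0.45), CD3D at 0.32 (SE 0.39), LCK at 0.19 (SE 0.24) and CD28 at 0.16 (SE 0.19). The 15 cytotoxic genes differed by 1.39, 0.81, -0.13, -0.37 and -1.25 (camera adjusted p = 0.583), with the granzyme GZMA at 0.44 (SE 0.33), CST7 at -0.56 (SE 0.44), EOMES at 0.21 (SE 0.18) and CCL5 at 0.21 (SE 0.63). The 12 checkpoint and exhaustion genes had a mean of -0.17 (camera adjusted p = 0.333), with ICOS at -0.43 (SE 0.29), ENTPD1 at -0.35 (SE 0.30) and the B-cell chemokine CXCL13 at -1.16 (SE 1.07). NK-cell and B- and plasma-cell lists had means of 0.16 and -0.01 (camera adjusted p = 0.386 and 0.929). Of 10 other inhibitory ligands, CD276, which encodes B7-H3, was the most abundant, at 76.8 ± 52.7 FPKM at baseline and 108 ± 72.8 on treatment (SD, n = 5), a log2 difference of 0.52 (SE 0.20). TNFRSF14 differed by 0.46 (SE 0.36) and C10orf54 by 0.27 (SE 0.23), and the list gave an adjusted p of 0.207.

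Regulatory T-cell genes rose relative to other genes (mean log2 change 0.35, 4 of 5 members higher, camera adjusted p = 0.046). The call was lost with an adjusted p = 0.991 (unadjusted 0.143) in camera with an estimated correlation. TNFRSF4, the costimulatory receptor OX40, led the list with 20.5 ± 22.2 FPKM at baseline and 36.4 ± 44.1 on treatment (SD, n = 5) and a log2 difference of 0.61 (SE 0.16), higher in 5 of 5 pairs. It was the only member to pass when adjusted over the list alone (adjusted p = 0.0326), and 0 members passed over all genes. IL2RA differed by 0.47 (SE 0.24) and TNFRSF18 by 0.60 (SE 0.58), while FOXP3, the lineage's transcription factor, differed by only 0.06 (SE 0.24) and CTLA4 by -0.0023 (SE 0.59), both named after their values were seen. The pair changes were 0.39, 0.68, -0.07, 1.36 and -0.61. In replicate 4, where the list was highest, TNFRSF18 was higher by 3.33 and CTLA4 by 2.57 but FOXP3 was at -0.10, and without that replicate the mean was 0.10 with an adjusted p of 0.426. Leaving out replicate 1, 2 or 3 also ended the call, with adjusted p of 0.115, 0.131 and 0.0901, as did the fit without the patient block, with 0.234. T-cell genes were at -0.34 in replicate 4. At baseline FOXP3 had a mean of 0.831 FPKM, against 13.6 ± 25.1 for CTLA4 (SD, n = 5). Bulk RNA does not tell which cells expressed these members, so the call is one of genes and not of cells.

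Genes of hypoxia and glycolysis fell relative to other genes (mean -0.39, 9 of 11 members lower, camera adjusted p = 0.00059), with an adjusted p = 0.991 (unadjusted 0.137) with an estimated correlation. BNIP3, a hypoxia-induced mitophagy receptor, had 30.5 ± 23.5 FPKM at baseline and 15.8 ± 10.5 on treatment (SD, n = 5), and the glucose transporter SLC2A1 and the kinase PDK1 differed by -0.55 (SE 0.21) and -0.59 (SE 0.24). These 3 genes were lower in all 5 pairs, and 0 members passed adjusted over the list alone. ENO1, the most abundant member, differed by 0.03 (SE 0.18). Pair changes were 0.04, 0.01, -1.36, -0.35 and -0.29, and without replicate 3 the mean was -0.15 with an adjusted p of 0.215.

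Proliferation genes fell relative to other genes (mean -0.24, 19 of 21 members lower, camera adjusted p = 0.00107), with an adjusted p = 0.991 (unadjusted 0.317) with an estimated correlation. BUB1, RRM2 and CDK1 differed by -0.51 (SE 0.27), -0.45 (SE 0.26) and -0.44 (SE 0.27), and PCNA, the most abundant, by -0.12 (SE 0.19). The pair changes were -1.26, -0.23, -0.29, 0.22 and 0.37, and 0 members passed over all genes or adjusted over the list alone. The call rested on replicate 1, whose libraries had the fewest genes above 0.5 FPKM: without it the mean was 0.02 and the adjusted p 0.932.

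Neutrophil genes fell relative to other genes (mean -0.41, 5 of 6 members lower, camera adjusted p = 0.00974), with an adjusted p = 0.991 (unadjusted 0.136) with an estimated correlation. The most abundant member, FPR1, had an estimate of 0.07 (SE 0.39). CSF3R, the receptor for granulocyte colony-stimulating factor, had 4.83 ± 4.78 FPKM at baseline and 2.43 ± 2.46 on treatment (SD, n = 5), a log2 difference of -0.66 (SE 0.33), CEACAM3 differed by -0.63 (SE 0.37) and MMP25 by -0.25 (SE 0.19). The pair changes were -0.45, 0.63, -0.999, -0.11 and -1.13. Without replicate 3 the mean was -0.27 with an adjusted p of 0.215, without replicate 5 it was -0.23 with 0.0962, and without replicate 2 it was -0.75. With each sample scaled to a total of 1000000 the mean was -0.13. Red-cell genes, another sign of blood in a biopsy, were at -0.02, 3.12, -3.08, 1.09 and -4.68 in the same pairs. Macrophage and monocyte genes, 13 of 16 with positive estimates, did not pass (mean 0.20, camera adjusted p = 0.159), with CD14 at 0.42 (SE 0.28), VSIG4 at 0.49 (SE 0.35), C1QA at 0.65 (SE 0.50) and C1QB at 0.60 (SE 0.49). That list passed without replicate 4, without replicate 5, with sample weights and with a total of 1000000. Its mean reached at most 0.47 over the alternatives. Dendritic-cell genes had a mean of 0.10 (camera adjusted p = 0.637).

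Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, rose relative to other genes (mean 0.45, 7 of 7 members higher, camera adjusted p = 0.00065), with an adjusted p = 0.991 (unadjusted 0.153) with an estimated correlation. HIST1H4H had 4.36 ± 4.46 FPKM at baseline and 7.40 ± 7.01 on treatment (SD, n = 5) and, like HIST1H4C, was higher in 5 of 5 pairs, with log2 differences of 0.55 (SE 0.22) and 0.39 (SE 0.18). HIST1H2BJ differed by 0.45 (SE 0.29) and HIST1H1C, the most abundant, by 0.57 (SE 0.42). The pair changes were 0.19, 0.43, 0.18, 1.65 and -0.19, and 0 members passed over all genes or adjusted over the list alone. Without replicate 4 the mean was 0.14 and the adjusted p 0.322, and with each sample scaled to a total of 1000000 they were 0.13 and 0.0894. In that replicate 7 other RNAs without a poly(A) tail differed by a mean of 4.21 (SE 1.78 over members), while the small nuclear RNA RNU4ATAC was at -5.03.

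Pigment-cell and stromal genes varied between biopsies without a common direction. The 17 melanocytic genes differed by -0.01, -0.35, 1.28, 0.46 and -0.41 (camera adjusted p = 0.282). RAB27A passed when adjusted over the list alone (adjusted p = 0.0282) and was the only member to do so, TYRP1 differed by -1.06 (SE 0.36), SLC24A5 by 0.54 (SE 0.31) and PMEL, the most abundant, by 0.75 (SE 0.95) although its mean FPKM was lower on treatment (1605 against 2668). The list of dedifferentiated melanoma had a mean of -0.09 (camera adjusted p = 0.672). The 14 fibroblast genes ranged from -1.56 to 2.13 between pairs (mean 0.26, camera adjusted p = 0.333), with MFAP5 at 0.65 (SE 0.50), FBLN1 at 0.53 (SE 0.59), SFRP2 at 0.53 (SE 0.66) and COL1A1 at 0.56 (SE 0.90). Endothelial genes ranged from -1.31 to 1.37, adipocyte genes from -2.27 to 2.01 and red-cell genes from -4.68 to 3.12, with adjusted p of 0.998, 0.998 and 0.333. The mean of the endothelial list was 0.02 where its median was -0.02 and camera's direction was down, and the adipocyte mean was 0.06 where camera's direction was also down. Keratinocyte, skeletal-muscle and hepatocyte lists had means of 0.33, 0.39 and 0.43 (camera adjusted p = 0.386, 0.130 and 0.333). Immediate early and stress genes had a mean of -0.13 (adjusted p = 0.672) and housekeeping genes one of 0.04 (adjusted p = 0.998). With 1 pair left out, fibroblasts passed without replicate 3 or 4 (mean up to 0.72) and melanocytic genes without 2 or 5 (up to 0.35). Without replicate 5 dedifferentiated (-0.38), endothelial (-0.32) and immediate early genes passed, as did skeletal muscle without 3 and red cells without 2. Adipocyte and housekeeping lists passed in none of these fits, nor did keratinocyte and hepatocyte lists where they were tested. Too few members were left to test keratinocytes without replicate 3 or 5, and hepatocytes without replicate 2 or 3.

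In all, camera with the preset correlation called 5 of 30 lists, and 0 were called with an estimated correlation or by fry, where the smallest adjusted p were 0.991 and 0.970. Unadjusted, camera with an estimated correlation gave the 5 called lists p between 0.136 and 0.317. The 0.991 that they share came with the adjustment over 30 lists. In the exact sign-flip permutation test over n = 5 pairs, the 5 called lists gave p between 0.25 and 0.562. Of 14 drawn splits of the samples that part all 5 pairs, the real one called the fewest lists, and the others called 7 to 19.

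**Figure D2:**
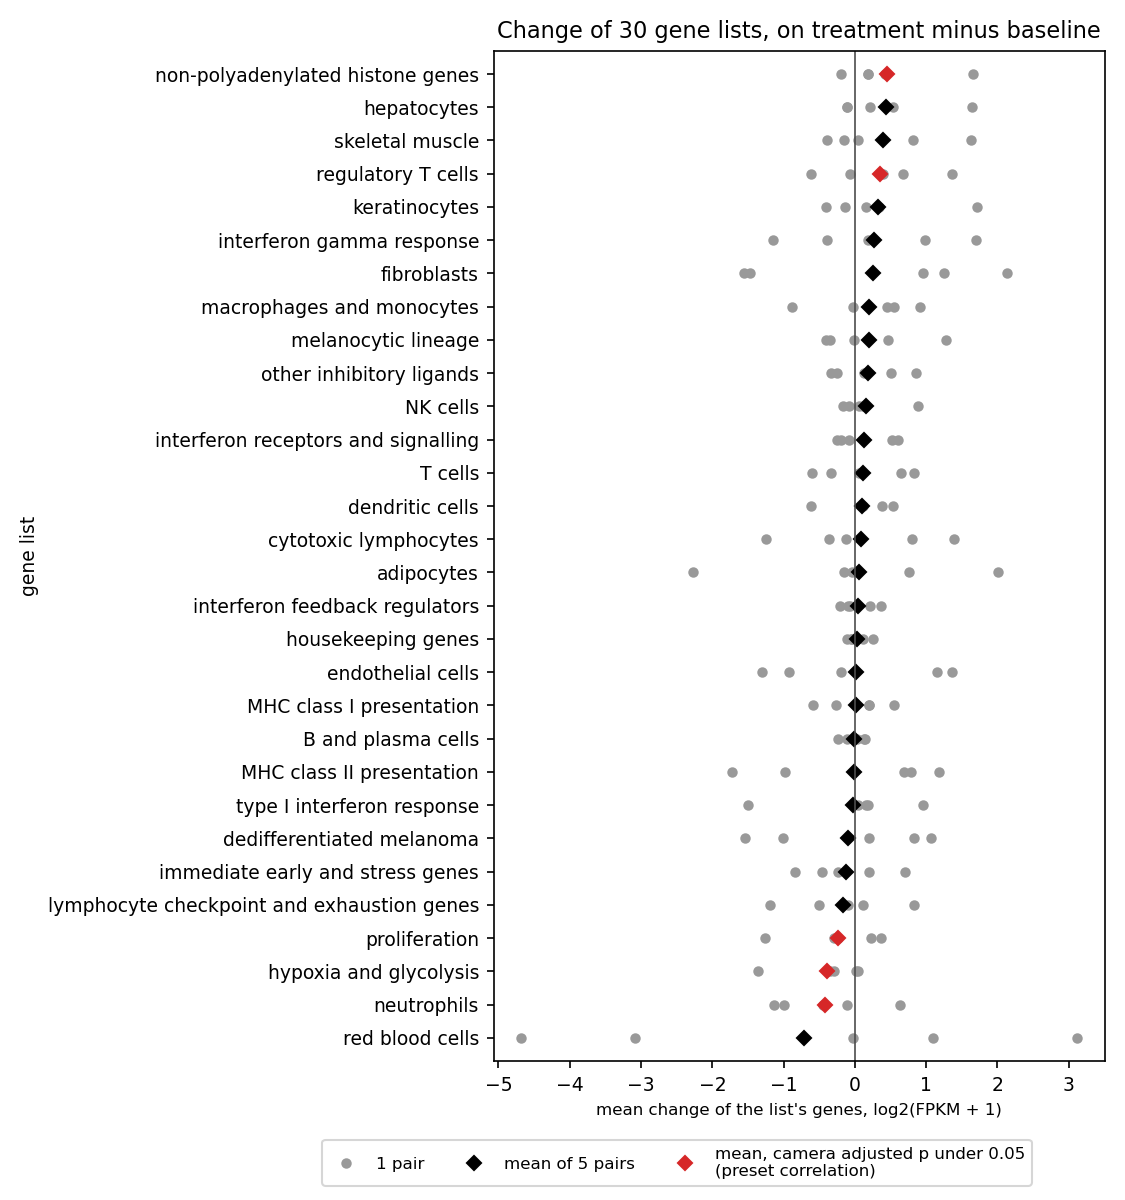
Change of 30 gene lists from baseline to on treatment (horizontal axis, mean over the list's genes on the log2(FPKM + 1) scale); grey points are the 5 pairs, diamonds their mean, red where camera with a preset correlation gave an adjusted p under 0.05. The pairs fell on both sides of 0 for every list, including the 5 in red, and the interferon gamma list ran from -1.15 to 1.70.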

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

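For 34 genes and 30 gene lists, each of the 2 groups of 5 samples was searched for a sample far from the others: a gap between an outermost sample and its neighbour above 0.71 of the group's range. Of 128 such groups 9 passed, where chance gives about 1 in 20, or 6.4. The tests below on tissue, red-cell, T-cell and melanocytic lists and on other RNAs without a poly(A) tail were chosen only after the result was seen.

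At baseline the lowest IFNGR1 sample lay apart (ratio 0.783), as did the highest sample of the adipocyte list (0.779). On treatment a highest sample lay apart for GPR153 (0.768), BEX5 (0.724), and the lists of checkpoint and exhaustion genes (0.725), B and plasma cells (0.754), keratinocytes (0.814) and skeletal muscle (0.793). For RNU4ATAC the ratio was 1, since the other 4 on-treatment samples were listed at 0.

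The interferon gamma list ran from 1.70 to -1.15 between pairs. Its SD over pairs, 1.12, exceeded that of all 10000 random lists matched on expression (highest 0.97, gene permutation p = 1e-04, the smallest these lists can give). A list whose genes vary together tends to exceed lists of unrelated genes. The test therefore shows only that these genes moved together (estimated correlation 0.743). The SD was larger for some other lists, such as fibroblasts (1.68) and red cells (3.15), and smaller for others, such as T cells (0.62). The interferon gamma list also kept a range of at least 2.79 under 3 other scalings, against 2.86 as deposited, with the sign of every pair as before. In replicate 5, where the list was lowest, fibroblast and endothelial genes were higher by 2.13 (SE 0.17 over members) and 1.37 (SE 0.14). These values argue against less of all non-melanoma tissue there. T-cell and macrophage genes were at -0.61 and -0.03, so a smaller share of immune cells stays open. An SE over members, here and below, treats genes that vary together as independent and holds no error between biopsies. In replicate 1, where the interferon gamma list was highest, endothelial genes did not rise with it, at -0.20 (SE 0.08). Fibroblast and macrophage genes were higher there, by 0.95 (SE 0.14) and 0.45 (SE 0.18), so that more of these cells stays open. The number of T cells in the biopsy remains open, since T-cell genes changed in the same direction in 5 of 5 pairs, which cannot be told apart from more interferon signalling per cell in bulk tissue, and the effect of treatment on single patients has no untreated pair to compare with.

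The lower proliferation, hypoxia and neutrophil lists may reflect genes that vary together: with an estimated correlation the smallest adjusted p of the 3 was 0.991. Unadjusted, camera then gave them p of 0.317, 0.137 and 0.136. In replicate 3, which carried the hypoxia call, melanocytic genes were higher by 1.28 (SE 0.39 over members) and dedifferentiated melanoma genes were at -1.54. A shift in tumour state could raise the former without more melanoma cells, so these values cannot decide whether there were fewer of them. Fibroblast, endothelial and immediate early genes were at -1.47, -0.92 and -0.84 there, so that a shift in other cells and tumour state stays open. In replicate 1, which carried the proliferation call at -1.26, melanocytic genes were at -0.01 (SE 0.16 over members), 9 of 17 upward. They give no sign of fewer melanoma cells there, but 1 pair cannot decide it. Over all pairs melanocytic genes differed by 0.20 (SE 0.31). Fewer melanoma cells therefore stay open for proliferation and hypoxia, but would not lower a neutrophil list. Less blood in the biopsies stays open for neutrophils, as red-cell genes differed by a mean of -0.71 (SE 1.41 over pairs). An effect of treatment also stays open.

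The higher histone list may come from 1 library with weaker poly(A) selection. In replicate 4, where the list differed by 1.65, 7 other RNAs without a poly(A) tail differed by 4.21 (SE 1.78 over members), 6 of them upward. Over all pairs these RNAs differed by 0.37 (SE 1.01), but in replicates 1, 2, 3 and 5 they were at 0.25, -1.14, -0.06 and -1.41 where the histone list was at 0.19, 0.43, 0.18 and -0.19, so the explanation could cover replicate 4 only. The small nuclear RNA RNU4ATAC went the other way in replicate 4, at -5.03, so the values there are mixed. Without that replicate the histone list was at 0.14 with an adjusted p of 0.322. Covariation of the list's genes is a further open explanation, with an adjusted p of 0.991 (unadjusted 0.153) in camera with an estimated correlation.

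Chance could not be excluded for the count of lists: all of 100 splits of the 10 samples into groups of 5 gave at least the 5 lists of the real split (highest other 22). For genes the real split called 0 (highest other 48), a count that every split reaches, so splits test nothing there. Among the 14 drawn splits that part all 5 pairs, as the real one does, the others called 7 to 19 lists and up to 39 genes. Splits that part fewer pairs rest on those pairs alone, and some of them repeat the same fit, so their counts compare less well. Whether the 39 genes of a split that parts all 5 pairs reflect a structure of the samples or chance was not tested.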

How the results depend on the processing

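The choices were made before the data were examined, except that leaving out small RNA genes and a total of 1000000 without them were added after seeing the data. The count of 0 called genes held in 16 of 17 alternatives. The exception was a total of 1000000, with 2 genes, SNORA65 and SNORA71A, where small RNAs set the totals, and 107 genes lay under an unadjusted 0.05. Without replicate 4 the latter count was 550. Without the patient block (no replicate block) 0 genes passed, 10 lay under an unadjusted p of 0.05 in place of 347, and 4 lists were called, without that of regulatory T cells. The pairing changed no other call. Of the interferon receptor and signalling genes 0 passed in all 17 alternatives. The difference between both interferon lists stayed positive in all 13, from 0.13 to 0.51. The number of called lists was 0 with an estimated correlation, 0 by fry, 3 under the stricter filter, where 24 lists had enough genes and neutrophils did not, 17 with a total of 1000000, 10 with sample weights, and 4 to 16 with 1 pair left out, the 16 without replicate 5, among them those of interferon receptors and signalling, T cells and cytotoxic lymphocytes. The regulatory T-cell list was also lost with no filter (adjusted p = 0.141), the stricter filter (adjusted p = 0.140), patient as a random effect (adjusted p = 0.212) and a total of 1000000 without small RNAs (adjusted p = 0.0582). With a total of 1000000 the histone list was lost (0.13, adjusted p = 0.0894), and the lists gained were interferon gamma, T cells, cytotoxic, other inhibitory ligands, NK cells, macrophages, dendritic cells, melanocytic, fibroblasts, keratinocytes, skeletal muscle, hepatocytes and red cells. Sample weights gained interferon gamma (0.40, adjusted p = 0.0145), other inhibitory ligands, macrophages, fibroblasts and skeletal muscle, and no filter gained skeletal muscle and hepatocytes. CD274 missed the stricter filter and has no value there. Over list results, 444 kept direction and side of the threshold, 24 lost and 39 gained a call, and 52 changed sign; of named-gene results 1408 kept both and 39 changed sign. Depth is unknown, so its effect could not be weighed.

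The following values took the opposite sign, none past an adjusted p of 0.05, and the cause was not tested. With a total of 1000000, PDCD1LG2 was at 0.10, the CD274 minus PDCD1LG2 difference at -0.00078, IFNGR2 at 0.059, JAK2 at 0.0087, HLA-DMA at 0.0079, CD28 at -0.048, MMP25 at 0.0034, PCNA at 0.019 and HIST1H2BJ at -0.0040. The lists of type I interferon response, MHC class II, checkpoint genes, B and plasma cells and dedifferentiated melanoma were there at 0.14, 0.21, 0.0083, 0.051 and 0.0071. With sample weights, PDCD1LG2 was at 0.038, IFNAR2 at 0.024, JAK2 at 0.052, and the MHC class II, B-cell and dedifferentiated lists at 0.17, 0.0048 and 0.063. With upper quartile scaling, IFNAR1 was at -0.00099, ENO1 at -0.023, and the feedback, MHC class I, endothelial and housekeeping lists at -0.0044, -0.026, -0.023 and -0.013. With quantile normalization, IFNAR1 was at -0.00056, FPR1 at -0.029, ENO1 at -0.11, and the feedback, B-cell and endothelial lists at -0.0049, 0.034 and -0.031. With a total of 1000000 without small RNAs, IFNAR2 was at 0.024, JAK2 at 0.0021, and the type I, MHC class II, B-cell and endothelial lists at 0.020, 0.037, 0.0078 and -0.0034. With a pseudocount of 0.1, FPR1 was at -0.00093, and the type I, MHC class II and endothelial lists at 0.034, 0.061 and -0.084. With no filter the dendritic list was at -0.0034.

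With 1 pair left out, these values changed sign in at least 1 case, given as lowest and highest. Past an adjusted p of 0.05 with the opposite sign were only the type I interferon and endothelial lists, at 0.34 and -0.32 without replicate 5. CD274 ran from -0.075 to 0.31 and was negative without replicate 1 or 2. PDCD1LG2 ran from -0.28 to 0.15 and was positive without replicate 3, 4 or 5. In the interferon pathway the ranges were -0.19 to 0.13 for IFNGR2, -0.081 to 0.24 for IFNAR1, -0.17 to 0.18 for IFNAR2 and -0.17 to 0.16 for JAK2. Among list members they were -0.034 to 1.06 for CD74, -0.44 to 0.17 for HLA-DMA, -0.088 to 0.63 for CD3D, -0.071 to 0.67 for CD3E, -0.34 to 0.81 for CCL5, -0.52 to 0.014 for ENTPD1, -0.080 to 1.04 for TNFRSF18, -0.36 to 0.40 for FPR1, -0.30 to 1.33 for PMEL, -0.22 to 0.021 for PCNA, -0.11 to 1.15 for SFRP2, -0.064 to 1.35 for COL1A1 and -0.048 to 0.13 for ENO1. For the lists of interferon gamma, type I interferon and feedback genes they were -0.10 to 0.62, -0.28 to 0.34 and -0.039 to 0.10. For MHC class I, MHC class II, T cells, cytotoxic and checkpoint genes they were -0.12 to 0.17, -0.31 to 0.42, -0.059 to 0.35, -0.23 to 0.45 and -0.49 to 0.040. For B cells, NK cells, dendritic cells, melanocytic and dedifferentiated genes they were -0.10 to 0.049, -0.046 to 0.37, -0.0076 to 0.28, -0.076 to 0.35 and -0.38 to 0.27. For proliferation, fibroblasts, endothelial cells and adipocytes they were -0.39 to 0.017, -0.21 to 0.72, -0.32 to 0.35 and -0.52 to 0.92. For red cells, immediate early and housekeeping genes they were -1.67 to 0.28, -0.34 to 0.047 and -0.021 to 0.073.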

Other observations

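CXCL9, a chemokine induced by interferon gamma, spread widely between patients, and was chosen here after its values were seen, as was IFNG. CXCL9 moved from 0.574 to 85.0 FPKM in replicate 1 and from 34.3 to 106 in replicate 2. It stayed near 0.488 and 0.480 FPKM in replicate 3, and moved from 1.67 to 0.904 in replicate 4 and from 39.5 to 17.3 in replicate 5. IFNG, the gene of the cytokine itself, was listed at 0 at baseline and at 0.843 FPKM on treatment in replicate 1, moved from 0.968 to 3.44 in replicate 2 and from 3.12 to 0.0635 in replicate 5, and lay at or below 0.0233 in replicates 3 and 4.

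The proliferation list had the opposite sign to the interferon gamma list in all pairs, with 0 of 5 in common, but so had the housekeeping genes, at 0 of 5. The lists of MHC class I and class II presentation, NK cells, macrophages and monocytes, T cells, other inhibitory ligands and also hepatocytes shared the direction of the interferon gamma list in 5 of 5 pairs, and the melanocytic and endothelial lists in 2 of 5. No p is given for these counts, and the shared directions are not particular to immune lists.

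A hypothesis, formed only after the values were seen, is that CD274 follows the interferon gamma list within a patient. CD274 and the interferon gamma list changed in the same direction in 5 of 5 pairs, and PDCD1LG2 and the list in 4 of 5. The ligands part only in replicate 3, where CD274 barely moved, from 0.132 to 0.149 FPKM, so these counts do not set them apart. These counts cannot decide the relation, since matching directions in 5 pairs cannot give a p under 0.05, and bulk RNA does not tell which cells expressed the ligands.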
